A study of Mus musculus with 10 samples.

How the data were processed

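RNA was taken from TH2 cultures on day 5 and made into stranded total RNA libraries with a globin-depleting TruSeq kit, per the labels' protocols. The deposited table holds raw read counts per Ensembl gene for 10 libraries, with 1 column per sample. Reads were processed with STAR 2.7.10a and HTSeq 0.13.5 on GRCm38, per the submitters' processing notes. The strand setting of the counting and the annotation release are not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. A total RNA library also counts unspliced and noncoding RNA, and reads that match several genes may be lost or split, which lowers genes with near-identical copies.

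The 49671 gene IDs of the table were matched to GENCODE release M21 (Ensembl 96, GRCm38) for symbols, gene types and coordinates. The match covered 49412 IDs, and the other 259 held 0.0226% of all counts. Libraries were assigned to diets by the treatment label and to batches by the batch label, and replicate numbers follow accession order and pair nothing. Totals per library ran from 5800698 to 13433276 counts, and the precision of low genes is set by the shallower control libraries.

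Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 13699, and scaled by TMM. A negative binomial quasi-likelihood model (glmQLFit, robust, and glmQLFTest) with terms for diet and batch was fitted to all 10 libraries. The common biological coefficient of variation was 12.7%. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. Batch was tested in the same fit, and a second fit added the product of diet and batch. Log2 fold changes are deficient minus control, with standard errors from the fit; levels are CPM on the plain library totals, and the principal components used log2 CPM on TMM-scaled totals. Single values between groups were compared by two-sided exact permutation tests over the 120 splits.

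A set of 35 gene lists, covering helper T cell programmes, vitamin D signalling, metabolism, stress and markers of other cell types, was fixed before the data were examined, as were the design, the alternative settings listed here and the rule for naming genes. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the 34 that had members tested. Of these, 8 passed, 4 upward and 4 downward, and 0 passed with an estimated correlation, with which 2 of the 8 had an adjusted p of 0.476, 1 of 0.154 and the rest of 0.92. fry, which asks whether the genes of a list move on balance one way, called 18, and its mixed test 32. The sign of the camera test differed from that of the median for 6 lists. Named genes are, in each direction, 12 among those of largest fold change with a mean of at least 1 CPM and 5 among those of smallest adjusted p. To these were added up to 4 members per list past the threshold (2 of smallest p where none passed) and the genes Vdr, Gata3, Il4, Il5, Il13, Il10, Ikzf3 and Ormdl3. The pseudogene Gm8730 had a fold and an adjusted p (7.07e-18, edgeR) beyond those of some genes so taken, but was not taken with them. Another 13 genes, Gm8730 among them, were chosen after their values were seen, and are marked as such or stand in the closing section. Abcg1, Cd8b1 and Ncr1 are named besides these, outside the rule.

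A fold against a group with 0 counts is a lower bound at 3 counts over the group, and genes with 1 to 3 counts have a ratio with a 95% counting interval. The share of each gene's sequence that occurs in another gene was measured by 50-base stretches of the annotated transcripts. The steps were tested on simulated counts with the real library sizes and 13699 genes for the comparison of deficient against control. There the test recovered 27 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 55 of 66 changed 4-fold, with 11 false calls among 159.

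Alternatives covered other scalings (median of ratios, upper quartile, total counts), no filter, a minimum count of 50, no robust estimation, DESeq2 1.42.0, limma-voom with and without quality weights, no batch term, each batch alone, 1 surrogate variable from sva 3.50.0, sex as a term, other thresholds, removal of small, ribosomal, mitochondrial and haemoglobin RNA, and each library left out in turn. Further alternatives were added after the data were seen: counts thinned to the depth of the shallowest library, male libraries only, fits without deficient libraries 5 to 7, and only genes that share no 50-base stretch with another gene. Figures were drawn with matplotlib 3.10.9.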

Results

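Gene expression was measured by RNA sequencing in mouse TH2 cells, the CD4+ helper T cells that secrete IL-4, IL-5 and IL-13 and drive allergic inflammation. Per the labels' protocols, naive CD4+ T cells of C57BL/6 mice were polarised in culture and harvested on day 5. The control mice ate a diet with 400 IU of vitamin D3 per kg, and the deficient mice were reared without ultraviolet light on a diet lacking vitamin D. The table held 3 libraries from control mice and 7 from deficient mice. Batch 1 contained 2 control and 5 deficient libraries, and batch 2 contained 1 control and 2 deficient libraries. The labels do not say that the libraries came from separate mice, so p-values here measure the spread between these samples, which may be technical.

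The control libraries held 5800698, 6237478 and 6462146 counts. Deficient libraries 1 to 7 held 12941782, 13192832, 7029207, 12790713, 12477182, 13433276 and 8526526 counts. Control libraries were the shallower group, at 6170000 ± 336000 counts (SD, n = 3) against 11500000 ± 2590000 counts (SD, n = 7; two-sided exact permutation p = 0.00833, the smallest that 120 splits can give). Replicates differed by more than sampling noise in every pair, with a chi-square per gene between 2.82 and 49.9, so none was treated as another library deposited again; this does not show that they came from separate mice. Xist, the RNA that silences an X chromosome in female cells, stood at 657 and 733 CPM in deficient libraries 1 and 3 and at 0.345 CPM or less in the other 8 libraries. Ddx3y, a gene of the Y chromosome, stood at 0.309 and 0 CPM in those 2 libraries. Neither gene passed the test between the diets (Xist adjusted p = 0.166, Ddx3y adjusted p = 0.482, edgeR), and 0 of the 5 sex-linked genes tested did; Ddx3y passed at -0.61 with sex as a term, and Xist passed with DESeq2.

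The libraries separated by diet along the first principal component, which held 67.6% of the variance. Correlations of log2 CPM across genes lay between 0.908 and 0.923 for pairs of libraries from different diets. Pairs of control libraries gave 0.982 to 0.986 and pairs of deficient libraries gave 0.968 to 0.993. The second component held 12.3% of the variance and spread the deficient libraries, with libraries 5, 6 and 7 at one end although library 5 carries the label of batch 1.

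**Figure D1:**
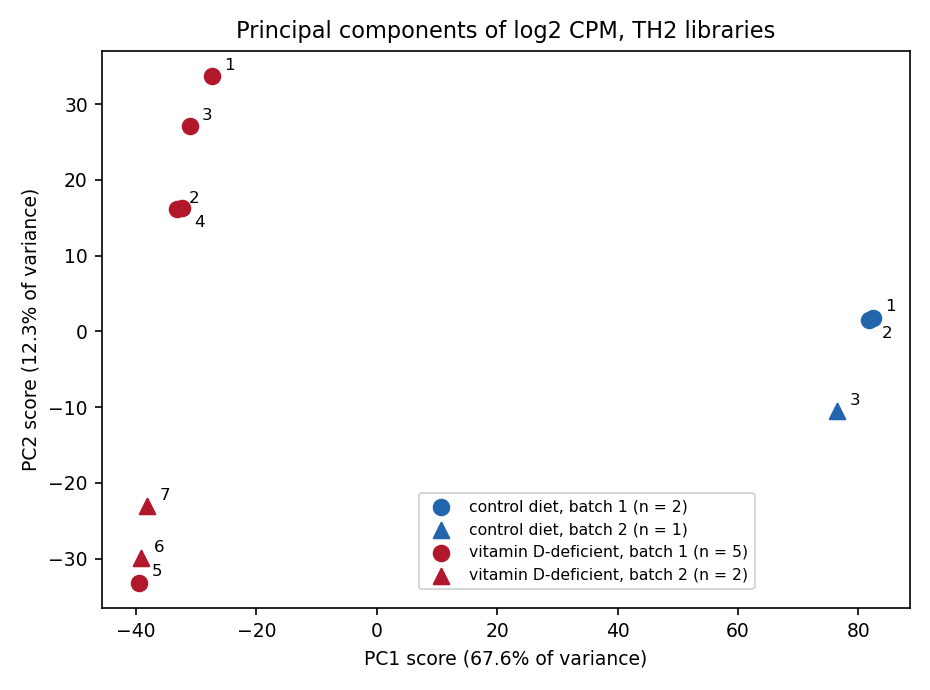
Scores of the 10 libraries on the first principal component (horizontal axis, 67.6% of the variance) and the second (vertical axis, 12.3%), computed from log2 CPM; colour gives the diet, the marker gives the batch and the digits are replicate numbers. The 3 control libraries lie apart from the 7 deficient libraries on the horizontal axis, and deficient library 5 of batch 1 lies beside the deficient libraries of batch 2.

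The first comparison asked which genes differ in TH2 cells between the diets. Differences named after the diet here may also come from another genetic background of the control mice or from library preparation. The closing section takes up both. The vitamin D receptor gene Vdr was lower in the deficient cells, at 3.73 ± 1.65 CPM (SD, n = 7) against 10.6 ± 0.657 CPM (SD, n = 3). Among TH2 cytokines, Il13 rose from 80.9 ± 17 to 200 ± 38.1 CPM and Csf2, which encodes GM-CSF, from 7.17 ± 1.78 to 165 ± 24.4 CPM, while Gata3, the master regulator of TH2 cells, fell from 62.0 ± 4.49 to 36.7 ± 3.95 CPM. Tbx21, the master regulator of TH1 cells, rose from 0.822 ± 0.333 to 38.0 ± 4.28 CPM. Of the cholesterol and fatty acid synthesis list 27 of 33 genes fell, and of the apoptosis regulators 17 of 27 rose (camera adjusted p = 3.36e-15 and 0.000121; adjusted p = 0.154 and 0.476 with an estimated correlation). Camera called 8 lists between the diets, and 55 of 100 splits of the libraries gave as many, so its calls alone are weak. Of 13699 genes tested, 4032 were higher and 3915 lower in the deficient cells (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), together 58.0%. A change of at least 2-fold was seen in 1409 higher and 1193 lower genes, and one of at least 8-fold in 277 and 136. Within batch 1, 3417 genes were higher and 3262 lower, and within batch 2, where the only control library is assumed to vary like the deficient ones, 3059 and 3038. Without deficient libraries 5 to 7, an alternative chosen after the data were seen, 3723 genes were higher and 3648 lower.

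Vdr (ENSMUSG00000022479, chromosome 15, 97854425 to 97910630 of GRCm38) had a log2 fold change of -1.68 (SE 0.277, adjusted p = 0.000156, edgeR), and each of the 7 deficient libraries lay below all 3 controls. The list of the vitamin D receptor and its metabolism had 13 members tested, of which 1 rose and 7 fell, and did not pass as a list (camera adjusted p = 0.105; 1 and 7 adjusted over the list alone). Falling members included the nuclear receptor coactivators Ncoa3 at -1.39 and Ncoa2 at -0.74 on the log2 scale, the corepressor Ncor1 at -0.64 and Dhcr7, an enzyme that turns the vitamin D precursor into cholesterol, at -1.66. Known target genes of the receptor went both ways: of 18 tested, 8 rose and 6 fell (8 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.893). Cdkn1a rose by 2.11 on the log2 scale and Txnip by 1.68, whereas Dusp10 fell by 2.10 and Ctla4 by 1.55.

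The TH2 genes did not move as a group. Of 35 members tested, 11 were higher and 13 lower (the same counts adjusted over the list alone), with a camera adjusted p of 0.887. The median log2 fold change was 0.05 and the mean 0.06, while the sign of the camera test was down. Csf2 (chromosome 11, 54247271 to 54249667) rose by 4.46 (SE 0.135, adjusted p = 2.49e-12) and Il13 (chromosome 11, 53631324 to 53634702) by 1.21 (SE 0.202, adjusted p = 0.000824). Il5 had a log2 fold change of 0.84 (SE 0.285, adjusted p = 0.0302) and missed the threshold without control library 1 (0.76), control library 2 (0.79), control library 3 (1.01) or deficient library 6 (0.83), within batch 1 (1.01), without the count filter (0.95) and without deficient libraries 5 to 7 (0.90). Il4 stood at 15.1 ± 0.617 CPM in controls and 16.5 ± 5.00 CPM in deficient cells (log2 0.05, SE 0.241, adjusted p = 0.868), a difference smaller than the spread between replicates, as was that of Il10 (-0.01, SE 0.286, adjusted p = 0.981), which passed within batch 2 at -0.60. Gata3 (chromosome 2, 9857078 to 9890034) fell by 0.84 (SE 0.0979, adjusted p = 3.33e-06). Also lower were the chemokine receptor gene Ccr4 (-1.06), Rad50 (-1.04), whose locus holds regulatory elements of the TH2 cytokine genes, and Asb2 (-2.19). Il1rl1, which encodes the IL-33 receptor and was chosen after its values were seen, fell from 23.4 ± 9.53 to 2.82 ± 1.65 CPM.

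More genes of TH1 cells were higher than lower in the deficient cultures. Of 27 members of the TH1 and interferon-gamma list tested, 16 rose and 5 fell (16 and 5 adjusted over the list alone), with a median log2 fold change of 0.95, also with Ly6c2, which had 0 counts in the controls, set at its bound. The list passed camera (adjusted p = 0.000716), with adjusted p = 0.92 with an estimated correlation. Tbx21 (chromosome 11, 97098071 to 97115331) rose by 5.45 on the log2 scale (SE 0.207, adjusted p = 1.96e-11), and the chemokine genes Ccl3 and Ccl4 by 6.60 and 5.41. Il18rap, a subunit of the IL-18 receptor, fell by 1.52. Ifng, chosen after its values were seen, stood at 4.48 ± 2.77 CPM in controls and 106 ± 69.5 CPM in deficient cells; deficient libraries 1 to 7 gave 36.8, 63.1, 56.3, 51.1, 198, 189 and 146 CPM.

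Markers of cytotoxic lymphocytes moved in the same direction. Of 14 members of the CD8 T and cytotoxic list tested, 11 rose and 0 fell at the adjusted p of edgeR (12 and 0 adjusted over the list alone), with a median of 2.96, unchanged with Klra4, which had 0 counts in the controls, at its bound (camera adjusted p = 0.00209; adjusted p = 0.92 with an estimated correlation). Gzmb, which encodes the protease granzyme B, rose from 73.5 ± 32.1 to 847 ± 269 CPM, and Klrd1, a receptor of natural killer and CD8 T cells, by 3.90 on the log2 scale. Cd8a, chosen after its values were seen, read 0, 0.641 and 1.55 CPM in the controls and 7.11, 10.8, 5.26, 9.23, 54.3, 50.8 and 35.3 CPM in deficient libraries 1 to 7. Its log2 fold change of 5.06 (adjusted p = 0.0191) missed the threshold without any 1 of the controls (4.72, 5.21 and 5.59 without controls 1, 2 and 3) and within batch 1 (5.58). Summed marker levels were 134 ± 56.7 CPM in controls and 1190 ± 454 CPM in deficient cells. Of the 15 members, 4 stand in another fixed list, and 8 had a control mean of at least 1 CPM.

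Among other cell types, the dendritic cell list passed with 6 of 10 tested members higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0328; adjusted p = 0.92 with an estimated correlation). That call was lost without deficient library 1 (adjusted p = 0.057; range over the alternatives with camera 0.00721 to 0.92). The members led by Batf3 (1.75), Zbtb46 (1.25) and Bst2 (0.88) summed to 82.7 ± 19.9 CPM in controls and 195 ± 76.2 CPM in deficient cells, and 5 of the 14 members stand in another fixed list. The B cell list did not pass (3 of 15 tested higher, 0 lower, 2 and 0 adjusted over the list alone; camera adjusted p = 0.134), but passed without deficient library 5 (adjusted p = 0.00367; range over the alternatives 0.00367 to 0.92) and without deficient libraries 5 to 7 (adjusted p = 0.025). Cd74, an MHC class II chaperone, rose by 4.92, and the immunoglobulin gene Ighm stood at 19.4 ± 16.2 CPM in controls and at 41.3, 50, 44.7, 49.4, 172, 159 and 179 CPM in deficient libraries 1 to 7. Ighm passed at 2.45 (adjusted p = 0.0133) and missed the threshold without control library 2 (2.23) and within batch 1 (2.73). Macrophage and monocyte markers summed to 105 ± 6.19 and 102 ± 19.7 CPM (5 of 9 higher, 1 lower; 5 and 2 adjusted over the list alone; camera adjusted p = 0.798). Mast cell and basophil markers (3 of 8 higher, 1 lower; 4 and 1 adjusted over the list alone; camera adjusted p = 0.407), erythroid markers (0 of 2; adjusted p = 0.887) and stromal markers (0 of 4 higher, 2 lower; adjusted p = 0.628) did not pass as lists. No neutrophil marker had enough counts to be tested (0.373 ± 0.174 and 0.871 ± 0.417 CPM summed).

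**Figure D2:**
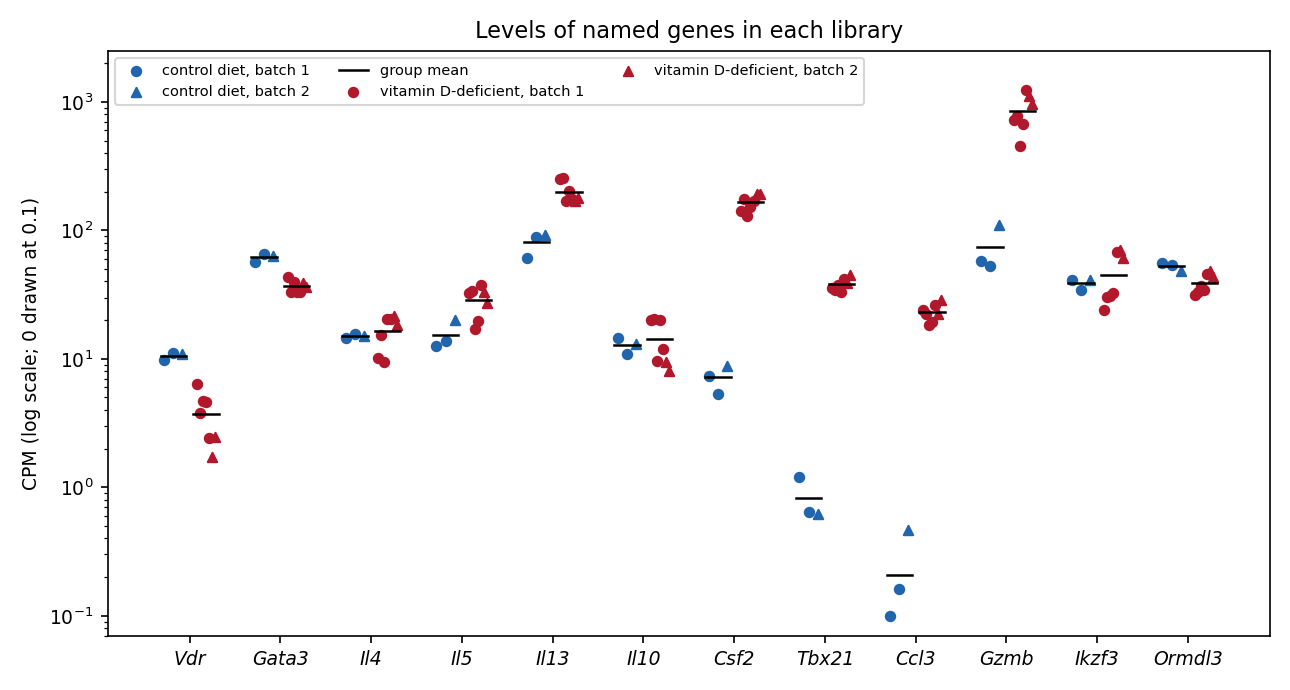
Level of 12 genes in each library, in CPM on a log axis with 0 drawn at 0.1; each point is 1 library, colour gives the diet, the marker the batch, and horizontal lines are group means. Tbx21, Ccl3, Csf2 and Gzmb lie higher in all 7 deficient libraries than in all 3 controls, Vdr and Gata3 lie lower, and the deficient values of Ikzf3 lie on both sides of the controls.

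Most genes of the lipid synthesis list fell. Of 33 tested members of the cholesterol and fatty acid synthesis list, 27 fell and 1 rose (27 and 1 adjusted over the list alone), with a median log2 fold change of -1.14 (camera adjusted p = 3.36e-15; adjusted p = 0.154 with an estimated correlation). Hmgcs1, the synthase at the start of the mevalonate pathway, fell from 435 ± 18.1 to 157 ± 12.8 CPM (SD, n = 3 and 7), Cyp51 from 351 ± 19.6 to 122 ± 6.81 CPM, and Mvd from 66.8 ± 7.33 to 15.7 ± 2.53 CPM. Nsdhl, an enzyme late in cholesterol synthesis, fell by 2.35 on the log2 scale (SE 0.0890, adjusted p = 1.96e-11). Each of these genes was lower in all 7 deficient libraries than in every control. The member that rose, Abcg1, encodes an exporter of cholesterol, and its log2 fold change was 1.08.

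More of the cell cycle genes fell than rose, and more of the apoptosis regulators rose than fell. Of 44 cell cycle genes tested, 26 fell and 8 rose (26 and 9 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.000716; adjusted p = 0.92 with an estimated correlation). The mitotic genes Kif23, Cenpa and Ube2c fell by 1.93, 1.52 and 1.47, and Mki67, a marker of dividing cells chosen after its values were seen, from 1310 ± 35.6 to 628 ± 138 CPM. Replication-dependent histones had 29 of 38 tested members lower and 1 higher (29 and 1 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.000716; adjusted p = 0.92 with an estimated correlation). Among them Hist4h4 fell by 2.10; many histone genes share sequence with near-identical copies, so their single values are uncertain, and the list was not called among genes that share no 50-base stretch with another gene (adjusted p = 0.534; range over the alternatives up to 0.92). Of 27 apoptosis regulators tested, 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.000121; adjusted p = 0.476 with an estimated correlation). The pro-apoptotic genes Bax, Bbc3 and Pmaip1 rose by 1.79, 1.64 and 1.30, and the cell cycle inhibitor gene Cdkn1a from 14.6 ± 3.01 to 67.1 ± 8.06 CPM.

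More of the T cell receptor signalling genes fell than rose. Of 29 tested, 16 fell and 5 rose (16 and 5 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.000716; adjusted p = 0.476 with an estimated correlation). Cd4 fell from 723 ± 13.8 to 335 ± 30.9 CPM, the signalling scaffold gene Malt1 by 1.47, Rasgrp1 by 1.03 and Plcg1 by 0.97. In the list of T cell activation and co-stimulation, 9 of 29 members rose and 9 fell (9 and 9 adjusted over the list alone; camera adjusted p = 0.887, direction down at a median of 0.13 and a mean of 0.24). Its co-stimulatory genes Icos and Cd28 fell by 2.35 and 0.92. Of 21 naive and resting T cell genes, 14 were lower and 5 higher (14 and 5 adjusted over the list alone), led by S1pr1 at 1.72, Lef1 at -0.59 and Klf2 at -2.78, and the list did not pass (camera adjusted p = 0.336). It passed without deficient libraries 5 to 7 (adjusted p = 0.017; range over the alternatives 0.017 to 0.92).

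**Figure D3:**
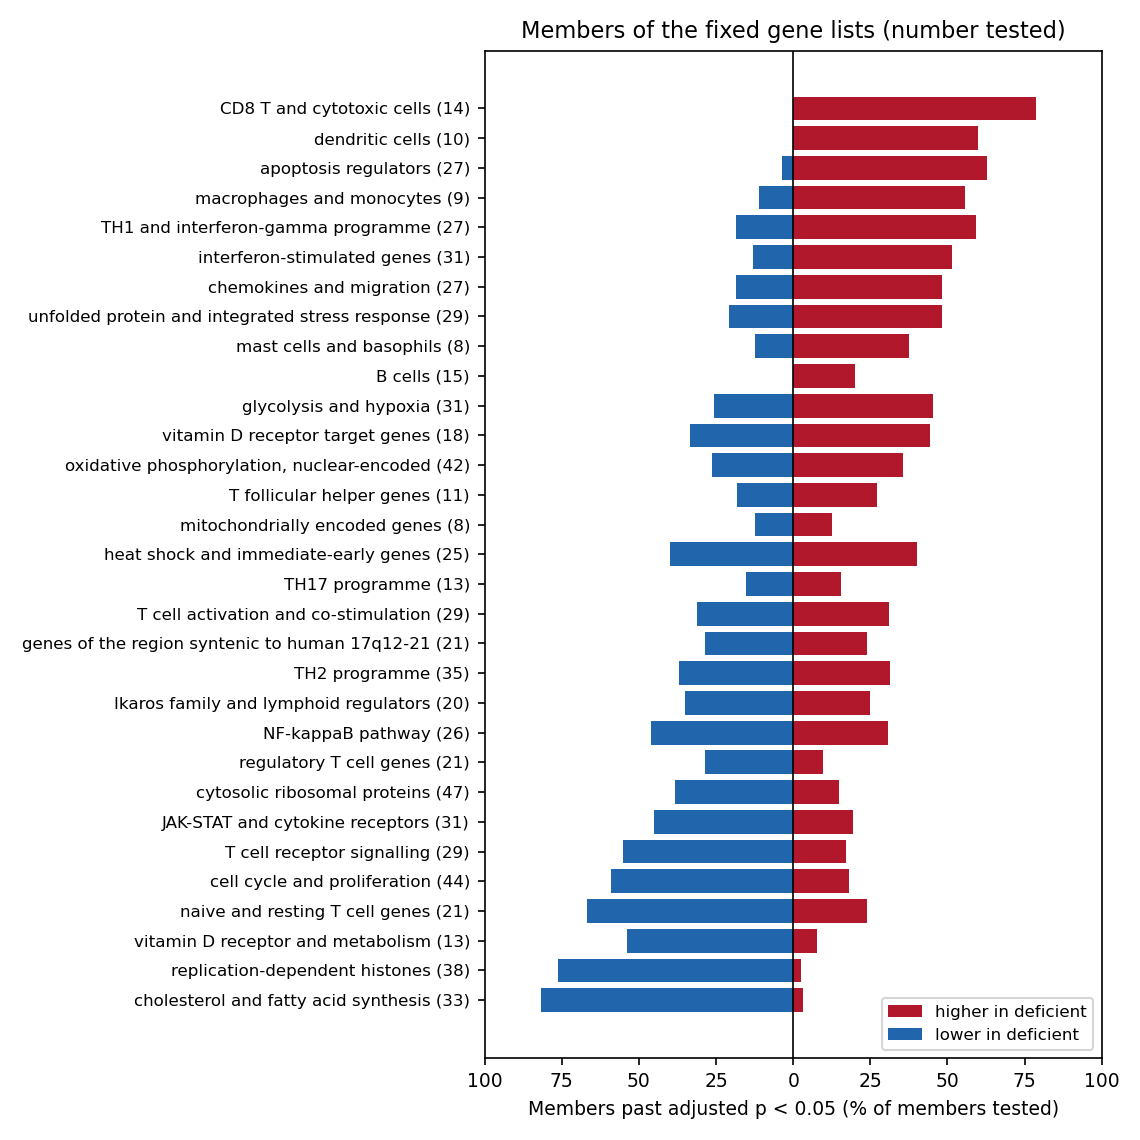
Share of the tested members of each fixed gene list that passed adjusted p < 0.05, in percent, for lists with at least 5 members tested and without the sex-linked list; bars to the right count members higher in deficient cells, bars to the left members lower, and the number tested stands in brackets. Cholesterol and fatty acid synthesis lies farthest down with 27 of 33 members lower, and the CD8 T and cytotoxic list at the top with 11 of 14 higher.

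The region of mouse chromosome 11 syntenic to the human asthma region on chromosome arm 17q was examined gene by gene. Of 21 genes tested there, 5 rose and 6 fell (5 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.798). Ormdl3 (ENSMUSG00000038150, 98581256 to 98587368), a regulator of sphingolipid synthesis, fell from 52.8 ± 3.83 to 39.0 ± 6.60 CPM (log2 -0.53, SE 0.123, adjusted p = 0.00241, edgeR); within batch 2 it missed the threshold at -0.15. Ikzf3 (ENSMUSG00000018168, 98464902 to 98546031), which encodes the lymphoid transcription factor Aiolos, had a log2 fold change of 0.11 (SE 0.348, adjusted p = 0.799). It read 40.9, 34.6 and 41.2 CPM in the controls and 24.2, 30, 30.7, 32.6, 67.6, 70.7 and 60.8 CPM in deficient libraries 1 to 7. Within batch 2 its change was 0.62 and passed the threshold, and without deficient libraries 5 to 7 it was -0.46 and passed in the other direction. Psmd3 rose by 0.55 and Med1 by 0.41, while Top2a, a replication gene, fell by 0.93 and Smarce1 by 0.58.

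**Figure D4:**
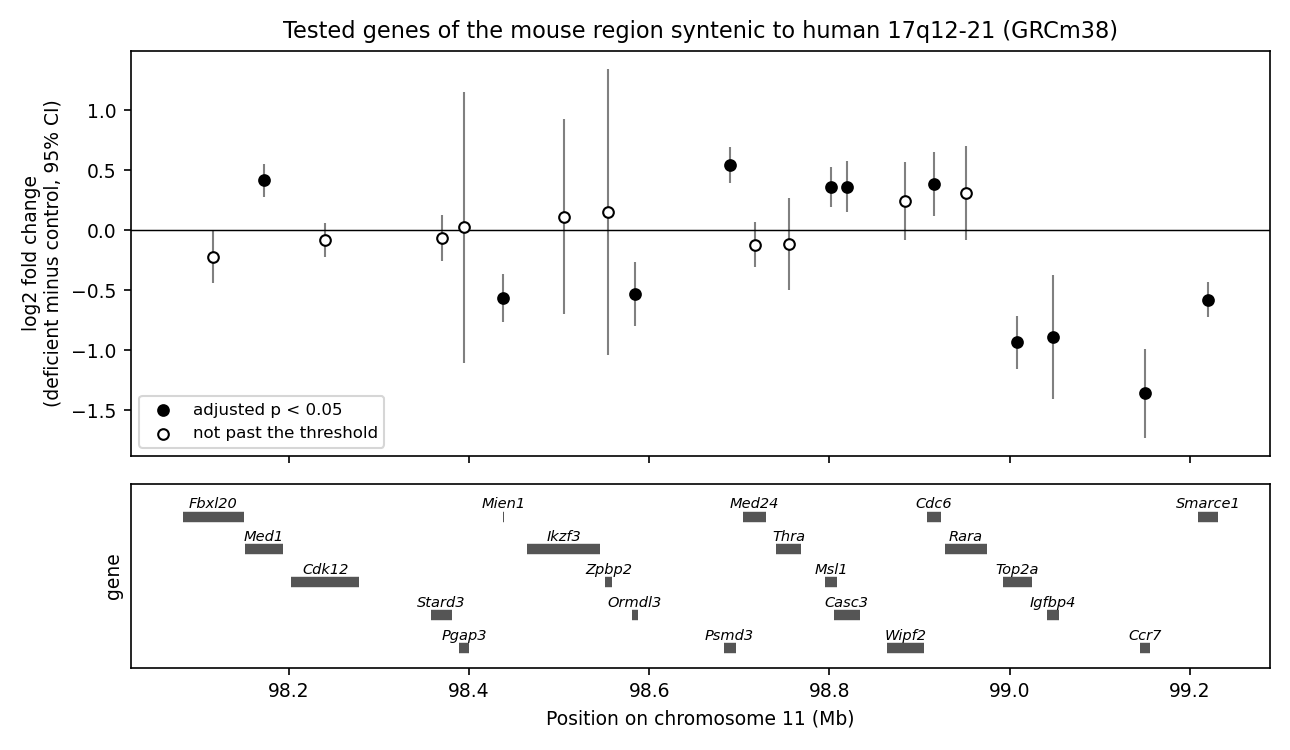
Log2 fold changes (deficient minus control, with 95% confidence intervals) of the 21 tested genes of the mouse chromosome 11 region, above a map of the genes to scale in Mb of GRCm38; filled points passed adjusted p < 0.05. Of the filled points 5 lie above 0 and 6 below, and the interval of Ikzf3 spans 0.

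The largest single changes were in genes at or near 0 in a group. Trim12a (chromosome 7, 104299894 to 104315466), of an antiviral TRIM family with similar neighbouring copies, had 0 counts in the controls and 34.1 ± 4.31 CPM in deficient cells, at least 212-fold higher with a floor of 3 counts over the control group. Its neighbour Trim30d had 3 control counts and a ratio of 210 (95% counting interval 71.8 to 1020). Ly6c2 was at least 30.1-fold higher, Ccl27a at least 28.1-fold, and the V segment Trav8-2 at least 17.6-fold. Il23a, a subunit of IL-23, had 2 control counts and a ratio of 297 (82.1 to 2450). Ly6a, which encodes the surface protein Sca-1, rose from 0.977 ± 0.297 to 296 ± 179 CPM, and Avil from 0.793 ± 0.540 to 185 ± 50.2 CPM. In the other direction Tnfrsf19 had a log2 fold change of -8.40 and the guanylate-binding protein gene Gbp2b one of -7.39. H60b, a ligand of the NKG2D receptor, had a ratio of 411 (139 to 2010), higher in controls. The RNA gene Rprl3 stood at 214 ± 15.3 CPM in controls and 0.0106 ± 0.0281 CPM in deficient cells (3100 to 682000 as the interval of a ratio of 17300). Intervals and floors cover counting error only.

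By adjusted p, the leading genes included Rpl26 (236 ± 14 to 1680 ± 72.9 CPM), the MHC class I gene H2-K1 (308 ± 15.7 to 1790 ± 141 CPM) and Plek (84.6 ± 2.58 to 624 ± 70.0 CPM) among those that rose. Emp1 (90.2 ± 3.47 to 1.45 ± 0.325 CPM), Sfi1 (507 ± 33.9 to 36.7 ± 2.41 CPM) and Ctse, which encodes cathepsin E (106 ± 11.3 to 6.82 ± 0.620 CPM), were among those that fell. They ranked behind Gm8730 and Rprl3 (adjusted p = 7.07e-18 and 1.88e-17, edgeR). Rpl26 shares 47.4% of its 50-base stretches and Rps3a2, which fell by 4.16, shares 90.2% with other genes, so reads could be split between copies and their values are uncertain. Processed pseudogenes took 0.648% ± 0.00850 of control counts and 0.191% ± 0.00692 of deficient counts (two-sided exact permutation p = 0.00833). Of 403 tested, 120 were lower and 26 higher in the deficient cells. The share called lower (29.8%) was like that of protein-coding genes (30%), of which 3480 of 11602 were lower and 3666 higher. The share called higher was smaller among the pseudogenes. The median log2 fold change was -0.26 for the pseudogenes and 0.03 for protein-coding genes. Gm8730, a pseudogene chosen after its values were seen, fell from 947 ± 21.5 to 15 ± 1.36 CPM and shares 73.7% of its stretches. Its adjusted p (7.07e-18, edgeR) was the smallest among the named genes.

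The comparison of batches asked how far the labelled batch moved expression. edgeR called 0 genes between the batches, with 1038 at an unadjusted p under 0.05 and a smallest adjusted p of 0.629, and DESeq2 and limma-voom also called 0. For a diet difference that depends on batch, edgeR called 0 genes, with 565 at an unadjusted p under 0.05 and a smallest adjusted p of 0.947, and DESeq2 and limma-voom called 0. Both counts rest on deficient library 5, without which 692 genes differed between the batches and 156 in the dependence of diet on batch.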

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

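The tests of a different genetic background, the comparison with Cd8b1, and the sex test for the spread among the deficient libraries, were chosen only after the results they address were seen, as were the fits on thinned counts, on male libraries only, without deficient libraries 5 to 7 and on genes with no shared stretch.

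Over the 7 deficient libraries 177 measures were examined for a library far from the others, and 6 had one whose gap to the nearest other exceeded Dixon's 95% critical value, against about 8.85 that chance gives. Hdgfl3 stood at 171 CPM in deficient library 4, with the others up to 151 CPM. Emp1 stood at 0.758 CPM in deficient library 2, with the others at 1.39 CPM or more. In deficient library 5 the interferon receptor gene Ifnar1 reached 129 CPM, with the others up to 116 CPM, and the histone gene Hist4h4 was lowest at 36.1 CPM, with the others at 44.4 CPM or more. Zbtb46, a transcription factor of dendritic cells, stood at 16 CPM in deficient library 7, with the others up to 12.4 CPM. Summed neutrophil markers reached 1.71 CPM in deficient library 3, with the others up to 0.985 CPM.

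Between the diets 7947 of 13699 genes differed. Lower depth of the controls, the sex of the animals and reads shared between near-identical copies are each argued against as the whole cause: 7394 genes were called with every library thinned to the smallest total, 7858 without the 2 libraries with Xist, and 58.1% of the 8581 genes with no shared 50-base stretch passed, against 45.9% of 617 genes that share over 50%. Random grouping of these libraries is argued against. Among 100 splits of the 10 libraries the real one, with 7947 genes, was the only 1 to call that many, and the highest other called 221. The splits treat each library as a separate sample, which the labels do not state. A chance difference between shared sources of the libraries is therefore not excluded. A different genetic background of the control mice may contribute, since germline T cell receptor V segments absent from a group are not what a diet is known to give: of 178 V segments, 34 of them annotated as pseudogenes, 2 were absent or nearly so from the controls, Trav16 (chromosome 14, 53743104 to 53743705; 1 count against 242) and its neighbour Trav8-2 (53738375 to 53738838, a pseudogene; 0 counts against 230), while 35 resampled splits of the deficient libraries gave 0 such segments. The 2 segments lie side by side, so they may stand for a single difference, other genes nearly absent from a group (Trim12a and Ly6a from the controls, H60b from the deficient libraries) were not tested for it, and the labels name a single strain, so a background difference, a difference in library preparation or sequencing between the groups, and the diet itself all stay open.

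Deficient libraries 5, 6 and 7 lay together and apart from the other 4 on the second principal component, although library 5 carries the batch label of the others, and markers of other cells moved with them: deficient libraries 1 to 7 summed to 96.2, 135, 98.2, 129, 477, 474 and 527 CPM for B cells, 921, 988, 648, 859, 1850, 1680 and 1400 CPM for CD8 T and cytotoxic cells, and 142, 143, 118, 137, 268, 279 and 282 CPM for dendritic cells. Sex is argued against as the cause: over autosomal genes the 2 deficient libraries of batch 1 that lack Xist and are not library 5 correlated better with the 2 that have Xist (0.987 to 0.989) than with the 3 others that lack it (0.977 to 0.982), a median difference of 0.0078. A batch label of library 5 that does not follow its preparation stays open, since 692 genes differed between the batches without that library against 0 with it. Control library 3, the control of batch 2, also had higher sums than controls 1 and 2. It gave 181 against 49.6 and 48.7 CPM for B cells and 199 against 104 and 97.6 CPM for CD8 T and cytotoxic cells. For dendritic cells it gave 105 against 68.1 and 74.7 CPM. All 100 splits of the libraries into groups of the sizes of the batches called at least the 0 genes of the real batches, as any split must, so they say nothing about chance, but the highest other, with deficient libraries 5, 6 and 7 as a group, called 2982, which points to a structure of the samples. A different share of other cells in these libraries stays open and was not tested, and no label names a biological difference between them.

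More genes of TH1 and cytotoxic cells were higher than lower in the deficient libraries, with Tbx21 at 38.0 ± 4.28 CPM against 0.822 ± 0.333 CPM. CD8 or other cytotoxic cells in the cultures could be a source and are not excluded. The 16 TH1 genes that rose had a median log2 range of 1.14 over the deficient libraries. This was a ratio of 0.34 to the range of Cd8a (3.37) and of 0.53 to that of Cd8b1 (2.13), the gene of the other CD8 chain. Single ranges went from 0.34 for Il12rb1 and 0.43 for Tbx21 to 2.43 for Ifng and 3.08 for Ccl5. Only Ifng and Ccl5 of the 16 varied more than Cd8b1, and none varied more than Cd8a. Tbx21 thus did not follow the CD8 genes over these libraries, but the test does not settle the set as a whole. Gzmb of the cytotoxic list stood among the 16 (log2 range 1.43), but that list as a whole was not tested in this way. Cells that lack CD8, such as natural killer cells, were not tested. Klrd1 rose by 3.90, and Ncr1, a receptor of natural killer cells, had a log2 fold change of -0.86 (adjusted p = 0.161, edgeR). The labels name naive CD4+ T cells as the starting cells. A different genetic background of the controls cannot be told apart from an effect of the diet here, because all controls may share it and only 2 of the 26 called genes had at most 3 counts over the controls. A shift of the cells toward TH1 with the deficient diet stays open as the biological explanation, and was not tested apart from these.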

How the results depend on the processing

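The fits on male libraries only, without deficient libraries 5 to 7, on thinned counts and on genes with no shared 50-base stretch were chosen after the data were seen. The numbers of genes higher and lower with the deficient diet (4032 and 3915) stayed within 1.5 times under all alternatives except 2: a fold change of at least 2 left 1409 and 1193, and genes with no shared stretch gave 2542 and 2432, where fewer genes were tested (8581). The other alternatives gave 3059 (batch 2 only) to 4793 (no count filter) higher and 3038 (batch 2 only) to 4364 (adjusted p below 0.1) lower genes, and leaving out 1 library at a time 3432 to 4107 and 3341 to 3988. No gene called as reported was called in the opposite direction under any of these alternatives; within batch 2, 25 had the opposite sign without passing. With total counts only, 4601 genes were higher and 3314 lower, and the median of all genes moved by 0.085 on the log2 scale; without the count filter 4793 and 3334 passed of 35136 tested, and the median moved by 0.109.

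The 8 gene lists that moved became 0 with an estimated correlation (0.0777 to 0.808 between the genes of these 8 lists), and 18 with fry, which asks another question. The other settings run for lists gave 7 to 9, and 11 without deficient libraries 5 to 7. The dendritic cell list was lost without deficient library 1, with the stricter count filter and without the batch term, and the histone list among genes with no shared stretch; the cause was not tested. Between batches 0 genes differed as reported and 183 without the count filter, and the dependence of the diet difference on batch went from 0 to 4 genes; the cause was not tested. Leaving out 1 library at a time gave 0 to 692 genes for batch and 0 to 156 for the dependence, both highest values without deficient library 5. The dependence was not run without control library 3, the only control of batch 2.

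Of 168 named genes, Ikzf3 (0.11 as reported, not called) reversed to -0.46 without deficient libraries 5 to 7 and passed. Up to 7 named genes lost their call in any single refit: 4, 7 and 6 without controls 1, 2 and 3, 6 within batch 1, and 3 within batch 2, where 3 others passed in addition. DESeq2 gave no adjusted p for 13 genes. No paired analysis was possible because the labels give no replicate numbers that the diets share. Small changes may be missed: on simulated counts 27 of 67 genes changed 1.5-fold were recovered. The simulation used the real library sizes only, so it does not separate depth from the number of libraries. It also changed a far smaller share of the genes than the 58% called in the data. The adjustment then sets a stricter cut, so recovery in the data may differ.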

Other observations

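The lists for p53 targets, ATF4 targets and the class I pathway were written after the data had been seen and before they were tested, and the fits without deficient libraries 5 to 7 and on genes with no shared stretch were chosen after the data were seen.

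The stress, energy metabolism and ribosomal lists that follow had members that moved in both directions, and camera called none of these 6 lists. Of 29 genes of the unfolded protein and integrated stress response, 14 rose and 6 fell (14 and 7 adjusted over the list alone; median 0.19, camera adjusted p = 0.266). Trib3, a stress-induced pseudokinase, rose by 1.44 and Phgdh, the first enzyme of serine synthesis, by 1.30, though it shares 63.1% of its stretches with other genes, while the protein disulfide isomerase gene Pdia6 and the transcription factor gene Xbp1 had changes of -1.24 and -1.14. Of 31 glycolysis and hypoxia genes, 14 rose and 8 fell (14 and 8 adjusted over the list alone; median 0.08, camera adjusted p = 0.26), with Gapdh going from 383 ± 2.30 to 830 ± 36.3 CPM and Ero1l rising by 1.24. Nuclear genes of oxidative phosphorylation had 15 of 42 higher and 11 lower (15 and 11 adjusted over the list alone; median 0.07, camera adjusted p = 0.798), among them Atp5g1 at 1.81 and Ndufv2 at -0.72. Of 8 mitochondrially encoded genes, mt-Cytb rose by 1.08 and mt-Nd2 fell by 0.69 (1 and 1 adjusted over the list alone; camera adjusted p = 0.887, direction up at a median of -0.07 and a mean of 0.03), and mt-Nd2 missed the threshold without control library 3 (-0.62), within batch 1 (-0.61) and without the count filter (-0.58). Heat shock and immediate-early genes gave 10 of 25 higher and 10 lower (11 and 10 adjusted over the list alone; camera adjusted p = 0.887, direction up at a median of 0.20 and a mean of -0.08), with Dusp2 at 1.47 and Jun, a component of AP-1, at -1.41. Of 47 cytosolic ribosomal protein genes, 7 rose and 18 fell (7 and 18 adjusted over the list alone; camera adjusted p = 0.798); their median of -0.07 is smaller than the 0.085 by which total count scaling moves all genes, and Rplp0 (1.04) and Rpl11 (-0.68) share 41.8% and 38.2% of their stretches with other genes.

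Among immune genes, 16 of 31 interferon-stimulated genes rose and 4 fell (18 and 4 adjusted over the list alone; median 0.88, unchanged with the gene at 0 in the controls at its bound; camera adjusted p = 0.26). Zbp1, a sensor of nucleic acids, rose by 2.02, whereas Ifi27l2a fell from 318 ± 3.77 to 77.2 ± 9.60 CPM. Of 27 chemokine and migration genes, 13 rose and 5 fell (13 and 5 adjusted over the list alone; median 0.85, camera adjusted p = 0.105, but 0.0457 among genes with no shared stretch; range over the alternatives with camera 0.0457 to 0.92). Of 31 JAK-STAT and cytokine receptor genes, 6 rose and 14 fell (6 and 14 adjusted over the list alone; median -0.11, camera adjusted p = 0.22, but 0.025 without deficient libraries 5 to 7; range over the alternatives with camera 0.025 to 0.92), with Jak2 at -0.75, both chains of the type I interferon receptor lower (Ifnar1 at -0.81 and Ifnar2 at -0.96) and Il21r at 0.86. NF-kappaB genes had 8 of 26 higher and 12 lower (8 and 12 adjusted over the list alone; camera adjusted p = 0.887, direction down at a median of -0.10 and a mean of 0.01), with Tnfrsf1b at -1.10 and Nfkbiz at 0.78. Of 21 regulatory T cell genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; median -0.18, camera adjusted p = 0.628): Tnfrsf18, which encodes GITR, fell from 690 ± 32.3 to 360 ± 16.4 CPM and Lag3 had a change of -0.97, while Ikzf2, which encodes Helios, rose by 2.39. In the T follicular helper list 3 of 11 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.798, direction down at a median of 0.35 and a mean of 0.12), with Cd200 at 0.85. In the TH17 list 2 of 13 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.919, direction down at a median of 0.01 and a mean of 0.15), with Ahr, the aryl hydrocarbon receptor gene, at -1.29 and Irf4 at 0.34. Ikaros family and lymphoid regulators had 5 of 20 higher and 7 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.887, direction up at a median of -0.15 and a mean of 0.01), with Ikzf1 at -0.55 and Ets1 at -0.87.

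The rise of Cdkn1a, Bax, Bbc3 and Pmaip1 raised the hypothesis that the p53 response differs between the diets. Of 28 further p53 targets tested that stand in no fixed list, 22 rose and 4 fell, with a median of 1.15 on the log2 scale (camera p = 5.56e-07; p = 0.0974 with an estimated correlation). Eda2r, a death receptor of the TNF family, rose by 3.42, the nuclease gene Aen by 2.00, and Ccng1, which encodes cyclin G1, from 521 ± 32.0 to 1430 ± 187 CPM. A stronger p53 response in the deficient cultures may contribute to the rise of the apoptosis regulators, but the test with an estimated correlation did not pass.

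A hypothesis of a different ATF4 response, a part of the integrated stress response, was tested on 27 genes outside the fixed lists. They were mostly amino acid and tRNA synthetase genes, with Vldlr, Nupr1, Stc2, Cebpb and Cebpg besides. Of the 27 genes, 21 rose and 1 fell, with a median of 0.41 (camera p = 1e-07; p = 0.0453 with an estimated correlation, or 0.136 adjusted over the 3 lists). Slc7a11, which imports cystine, rose by 2.84 and Slc1a5, which imports glutamine, by 1.56. The counts are consistent with a stronger response of this kind in the deficient cultures, and the adjusted value does not pass.

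After H2-K1 was seen among the leading genes, a hypothesis that the class I antigen presentation pathway differs was tested on 14 genes without the heavy chains. Of these, 9 rose and 3 fell, with a median of 0.43 (camera p = 0.00263; p = 0.295 with an estimated correlation). B2m, the light chain of class I molecules, rose from 611 ± 44.1 to 1730 ± 279 CPM and the peptide transporter gene Tap1 by 1.14. A higher class I pathway in the deficient cultures may be real, but the call was lost with an estimated correlation.

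Processed pseudogenes took a lower share of the counts in the deficient libraries, with 120 of 403 lower and 26 higher. The share of them called lower, 29.8%, was like the 30% of protein-coding genes, of which 3666 of 11602 were higher. The share called higher was smaller among the pseudogenes, and their median log2 fold change was -0.26 against 0.03 for protein-coding genes. Whether pseudogenes differ from other genes in these counts was not tested. A hypothesis that reads of processed pseudogenes were counted for near-identical copies instead predicts higher values of the genes they match. The test cannot decide it. These pseudogenes took 0.648% of control and 0.191% of deficient counts, so moved reads could be too few to shift the median of the matching genes. The 85 best-matching protein-coding genes tested had a median log2 fold change of -0.15, with 31 higher and 42 lower, inside the range of -0.18 to 0.05 that spans the 5th to 95th percentiles of 10000 random sets. Lower pseudogenes shared a median of 60.8% of their stretches with other genes and those not called 61.1%. The cause stays open, and a difference in library preparation between the groups was not tested.

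The number of gene lists that moved, 8, is one for which chance cannot be excluded: 55 of 100 splits of the libraries gave as many. The other splits had a median of 8 and a highest value of 19. Why so many lists moved in them was not tested.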
